A study of Mus musculus with 3 samples.

How the data were processed

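Small RNA was sequenced from B16 mouse melanoma cells, from exosomes of B16 cells and from exosomes of JB6 mouse skin cells, with 1 library each. Per the labels' protocols, exosomes were harvested by ultracentrifugation, RNA was extracted with Trizol, and libraries were made with the manufacturer's standard protocol and run on an Illumina HiSeq instrument. The submitters' processing notes name bcl2fastq, BWA and the mouse build mm10. Their versions, the adapter and length settings, the miRNA annotation release, the use of strand and the treatment of reads that match several miRNAs are not given in the sources used here.

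Each of the 3 deposited files lists 1915 mature miRNAs with a count of reads, which the authors made before depositing and which is not normalized, per the file headers. The smallest count above 0 was 10 in every file, so the deposited counts show that values below 10 are listed as 0. Each file also holds a normalized value in RPM that the authors computed. Within each file it equals the count times a constant, and the total behind it is larger than the sum of the miRNA counts, at 8721363 in B16 cells, 847694 in B16 exosomes and 5626936 in JB6 exosomes. What that total counts is not given in the sources used here. No entry lacked a miRNA name. In JB6 exosomes 10 reads equalled 2.22 RPM of miRNA reads, in B16 cells 1.26 RPM and in B16 exosomes 218.9 RPM, so a miRNA at a low share can be seen in the deep libraries and not in the B16 exosome library.

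Groups came from the labels. The comparisons were B16 exosomes against B16 cells, B16 exosomes against JB6 exosomes, and the overlap of miRNAs higher in each exosome library than in B16 cells. With 1 library per group, no spread between samples can be estimated, so no test across libraries was run. For each miRNA with 30 or more reads over the pair of libraries, the ratio of its shares of total miRNA reads was computed from the counts with an exact (Clopper-Pearson, conditional binomial) 95% interval. Sequencing reads without molecular identifiers are not independent molecules, so the intervals cover counting error only. A miRNA was called higher or lower when the ratio was at least 2-fold and the interval excluded 1. A listed 0 was set to 9 reads, which gives a bound ("at least N-fold"), and a miRNA whose bound did not reach the rule was called not resolved. Each such bound is the ratio at 9 reads and leaves out counting error. The counting interval around it reaches closer to 1. The comparisons, the size rule, the minimum, the miRNA lists, the naming rule and most alternatives were fixed before the data were examined. The treatment of a listed 0 was added once the files showed that small counts were left out.

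The lists, 23 in all, covered miRNA families (let-7, miR-17-92 and paralogues, miR-30, miR-34, miR-29, miR-15/16, miR-181, miR-10 with miR-99/100 and miR-125, miR-23/27/24), genomic clusters (Dlk1-Dio3, Sfmbt2, miR-290 and miR-302, H19 and Igf2), cell types (melanocyte lineage, epithelial and keratinocyte, mesenchymal and fibroblast, erythroid, leukocyte, and liver, muscle and brain) and other themes (melanoma-associated, hypoxia, non-canonical biogenesis, and entries resembling rRNA or tRNA fragments). Some miRNAs stand in more than 1 list, such as miR-30d-5p and miR-30b-5p in the miR-30 and melanoma-associated lists. The median log2 ratio of a list was planned over all members with 30 or more reads. Because a listed 0 in the shallow library sets that ratio at a fixed count, the median was instead taken over members whose mean share predicts at least 20 reads in the shallower library, and only with 3 or more such members. Under the planned form the medians of the first comparison were 0.26 for miR-17-92, 1.80 for the melanocyte list and 0.37 for the melanoma-associated list, and those of the miR-30, let-7 and miR-23/27/24 lists did not move. For Dlk1-Dio3 and for liver, muscle and brain in the exosome comparison, and for Dlk1-Dio3 in JB6 exosomes against B16 cells, the planned form is reported, because a member with a listed 0 passes that filter only when its share in the other library is high. Each median was placed among 10000 random lists of the same size and matched abundance, as a description of these libraries.

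Named miRNAs were the 10 most abundant of each library, the 12 with the highest and the 12 with the lowest ratio of each comparison by the interval bound nearest to 1 among those that met the rule with 100 or more reads in whichever library had the larger raw count, up to 4 of the most abundant members of each list, and miR-690, miR-155-5p, miR-21a-5p and miR-211-5p. Other list members that are named, and the miRNAs higher or lower in both exosome libraries, lie outside this rule and were chosen after their values were seen. The alternatives were TMM factors, DESeq2 size factors, totals without the 10 most abundant miRNAs, minimums of 10, 100 or no reads, an interval bound of at least 2-fold, and near-identical family members summed. The authors' totals as scaling, and libraries thinned to the B16 exosome depth, were added after the data were seen. edgeR 4.0.16 and DESeq2 1.42.0 in R 4.3.3 were used for scaling factors only. Other steps used Python 3.11.15 with numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9.

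The ratios were tested on simulated Poisson counts at the real depths, drawn from the summed read counts of each pair of libraries. In the pairs with B16 exosomes the simulated profile was therefore mostly that of the deeper library. The 40 most abundant miRNAs were kept unchanged, and 200 of the others were changed. For B16 exosomes against B16 cells, 564 miRNAs were simulated, the intervals held the true ratio for 93.0% of miRNAs with a count in both, and 56 of the 200 changes were resolved. Those called in the direction set were 7 of 53 at 8-fold lower, 9 of 48 at 4-fold lower, 22 of 47 at 4-fold higher and 18 of 52 at 8-fold higher. So outside the 40 most abundant miRNAs most changes, and lowered miRNAs above all, are missed at this depth. Changes among the most abundant miRNAs were not simulated. Of 97 unchanged miRNAs that were resolved 97.9% were left uncalled. For B16 against JB6 exosomes, with 405 miRNAs, coverage was 94.4%, 54 of the 200 changes were resolved, 5 of 53, 6 of 48, 19 of 47 and 24 of 52 at the same sizes were called in the direction set, and 98.4% of 62 resolved unchanged miRNAs were left uncalled. For JB6 exosomes against B16 cells, with 640 miRNAs, coverage was 94.7%, 155 of the 200 changes were resolved, and 34 of 53, 27 of 48, 43 of 47 and 50 of 52 were called in the direction set. None was called in the opposite direction.

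Coordinates are 1-based in GRCm38, the assembly that mm10 names, from GENCODE release M21. Of 644 miRNAs listed in any library 614 (95.3%) matched an annotated hairpin gene by name. Mature miRNAs made from several hairpins cannot be assigned to one of them. miR-199a-3p and miR-199b-3p, let-7a-1-3p and let-7c-2-3p, and miR-486a-5p and miR-486b-5p had identical counts in every library and are uncertain as separate miRNAs. Reads outside the miRNA tables, JB6 cells and untreated culture medium were not analysed here.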

Results

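Small-RNA sequencing libraries from 3 sources were compared. B16 cells, a mouse melanoma line labelled as strain C57BL/6J, gave a cell library and a library from the exosomes that they release. JB6 cells, a mouse skin line labelled as normal and as strain BALB/c, gave an exosome library. Exosomes are small vesicles shed into the culture medium, and here they had been collected by ultracentrifugation. Each group held 1 library, so no difference has a replicate check, and every interval covers counting error only. The libraries differed greatly in depth. Reads assigned to mature miRNAs numbered 7925726 in B16 cells, 45677 in B16 exosomes and 4495956 in JB6 exosomes. Of 1915 miRNAs, 559, 149 and 389 were listed above 0, and no listed count was below 10 reads. A listed 0 therefore stood for at most 9 reads, which is 1.14 RPM of miRNA reads in B16 cells, 197 RPM in B16 exosomes and 2.002 RPM in JB6 exosomes. Thinned to the depth of the B16 exosome library, a setting added after the data were seen, the B16 cell library listed 136 to 150 miRNAs over 100 draws and the JB6 exosome library 91 to 102.

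The B16 libraries were dominated by the same families, and the JB6 exosome library was not. let-7i-5p, a member of the let-7 family that restrains growth-promoting genes, was the most abundant miRNA of both B16 libraries, with 15.7% of the miRNA reads of the cells (exact 95% interval 15.67 to 15.72) and 17.5% of those of the exosomes (17.2 to 17.9). In JB6 exosomes miR-122-5p, the predominant miRNA of liver, held 25.1% (25.08 to 25.16), and miR-148a-3p, which is abundant in liver and milk, held 21.8% (21.75 to 21.83). The summed let-7 family held 35.8% of reads in B16 cells, 38.0% in B16 exosomes and 3.60% in JB6 exosomes. The miR-30 family held 14.3%, 8.92% and 0.699%. miR-21a-5p, a miRNA raised in many tumours, held 5.87%, 3.65% and 0.896%. The 10 most abundant miRNAs took 59.3% of the reads of B16 cells (59.3 to 59.4), 61.0% of B16 exosomes (60.6 to 61.5) and 74.4% of JB6 exosomes (74.3 to 74.4). miR-10b-5p and miR-143-3p were among the 10 in all 3 libraries. miR-10b-5p held 3.13%, 3.84% and 4.15%, and miR-143-3p held 3.60%, 7.61% and 3.22%. let-7f-5p, let-7g-5p, let-7c-5p, miR-30a-5p, miR-30d-5p, miR-21a-5p and miR-7a-5p completed the list of both B16 libraries. In JB6 exosomes the list was completed by miR-92a-3p, miR-423-5p, miR-99b-5p, miR-151-3p, miR-10a-5p and miR-99a-5p.

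**Figure D1:**
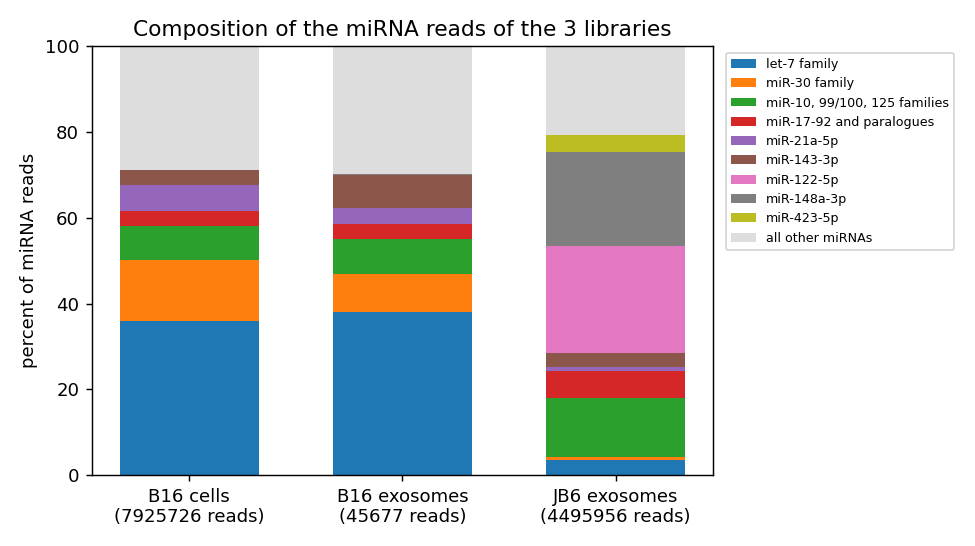
Stacked bars give the percent of the miRNA reads of each library held by 4 families and 5 single miRNAs, with 1 library per bar. The let-7 family takes 35.8% of the B16 cell reads, 38.0% of the B16 exosome reads and 3.60% of the JB6 exosome reads, where miR-122-5p takes 25.1% and miR-148a-3p 21.8%, all as shares of miRNA reads.

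The B16 exosome library was set against the B16 cell library, which asks which miRNAs of the melanoma line are over- or under-represented in its vesicles. Several miRNAs that were scarce in the cells were among the more frequent ones of the exosomes. The share of miR-690 was 857-fold higher in the exosomes (671 to 1105), that of miR-6538 was 601-fold higher (495 to 734), that of miR-677-5p 114-fold higher (89.0 to 146) and that of miR-1957a 102-fold higher (93.0 to 111). miR-30c-5p, a member of the miR-30 family, was 6.19-fold lower (5.21 to 7.41), and miR-27a-3p, of a cluster with miR-23a and miR-24, was 4.46-fold lower (3.47 to 5.85). The most abundant let-7 members lay within 2-fold, with ratios of 1.12 for let-7i-5p (1.09 to 1.14) and 1.59 for let-7f-5p (1.54 to 1.64).

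Of 422 miRNAs with 30 or more reads over these libraries, 36 were higher and 33 lower by a size rule of 2-fold with an interval that excluded 1, 86 were neither, and 267 with a listed 0 in the exosomes were not resolved, because their bound did not reach the rule. Scaling set the balance of higher and lower. TMM factors gave 16 higher and 93 lower, and the authors' totals gave 9 and 257. Against the main scaling, TMM moved every log2 ratio by -1.02, DESeq2 size factors by -0.13, a total without the most abundant miRNAs by 0.08 and the authors' totals by -4.08. A lower call from a listed 0 in the exosomes needed at least 3124 reads in the cells. Across the 144 miRNAs listed in both libraries the shares correlated with a Spearman coefficient of 0.75 and a Pearson coefficient of 0.72 on the log2 scale, where miRNAs are not independent replicates.

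The miRNAs with the largest excess in the B16 exosomes rested on moderate counts. miR-1957a had 804 reads in the exosomes and 1373 in the cells, miR-6538 had 464 and 134, miR-690 had 390 and 79, and miR-677-5p had 110 and 167. In the mouse genome build GRCm38 each of these hairpins lies in an intron of a protein-coding gene. Mir690 lies at chromosome 16, 28599935 to 28600043, in Fgf12, Mir6538 at chromosome 12, 26414901 to 26415010, in Rnf144a, Mir1957a at chromosome 4, 119129779 to 119129844, in Slc2a1, and Mir677 at chromosome 10, 128085286 to 128085363, in Atp5b. The Mir677 hairpin is also annotated as a snoRNA, and stretches of the Mir690 and Mir3473a hairpins recur in 27 and 219 other annotated genes. miR-3473a was 42.4-fold higher (29.6 to 59.5). miR-100-5p, a relative of miR-99a, was 24.8-fold higher (21.6 to 28.5), with 239 reads against 1670, and miR-148a-3p was 20.8-fold higher (16.7 to 25.6), with 98 against 819. Both fell short of the 2-fold rule under the authors' totals. miR-199a-5p at 13.7-fold (7.13 to 24.03), miR-5100 at 10.8-fold (5.81 to 18.5), miR-122-5p at 9.89-fold (6.27 to 14.9) and miR-3535 at 7.39-fold (5.31 to 10.02) were higher too, on 13 to 43 exosome reads, and their ratios fell below 1 under the authors' totals. For miR-122-5p the excess stays open to carry-over from the JB6 exosome library, weighed below. miR-5126, which the naming rule did not select and which was picked after its values were seen, was the only higher miRNA listed at 0 in the cells, with 52 reads in the exosomes and a share at least 1003-fold higher. With counting error, the interval limit nearest to 1 was 490-fold.

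Among the lower miRNAs, miR-24-3p and miR-3074-5p were 3.87-fold (3.35 to 4.49) and 4.42-fold (3.40 to 5.85) lower. Their hairpins overlap on opposite strands at both genomic copies, so their counts are uncertain unless strand was used in the counting. miR-484, which is made without the Drosha enzyme, was 3.87-fold lower (2.66 to 5.88), miR-32-5p was 3.50-fold lower (2.22 to 5.92), miR-99b-5p was 2.63-fold lower (2.21 to 3.15) and let-7d-5p was 2.58-fold lower (2.12 to 3.18). miR-27a-5p, with 10401 cell reads and a listed 0 in the exosomes, was at least 6.66-fold lower, taking 9 reads for the listed 0. let-7a-1-3p and let-7c-2-3p were at least 4.87-fold lower. They had identical counts in each library, so they are uncertain as separate entries among the lower miRNAs. miR-211-5p, a melanocyte miRNA that lies in an intron of Trpm1 (chromosome 7, 64205806 to 64205911), had 83 reads in the exosomes and 21080 in the cells, a ratio of 0.683 (0.544 to 0.847). The ratio of miR-21a-5p was 0.621 (0.592 to 0.652). miR-155-5p, an immune-cell miRNA, had 375 reads in the cells and a listed 0 in the exosomes, and was not resolved.

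The fixed miRNA lists were described by how many members with 30 or more reads met the size rule and, where at least 3 members could be evaluated at this depth, by their median log2 ratio. Of 5 miR-30 members 3 were lower and none higher, with a median of -1.22 at percentile 0.93 of 10000 random lists of matched abundance, and 5 were lower under the authors' totals. miR-30d-5p was 2.55-fold lower (2.42 to 2.68) and miR-30e-5p 2.32-fold lower (1.81 to 3.04), while the ratio of miR-30a-5p was 1.33 (1.28 to 1.39). Of 5 members of the miR-23/27/24 clusters 3 were lower and none higher, with a median of -1.11 (percentile 10.1), and 4 were lower with TMM and 5 under the authors' totals. Their ratios ran from 0.678 for miR-23a-3p and 0.462 for miR-27b-3p down to the values of miR-24-3p and miR-27a-3p. Of 5 mesenchymal miRNAs 3 were higher, with a median of 1.08 (percentile 95.9) that turned to -2.99 under the authors' totals, where none was higher and 4 were lower, and 1 was higher and 1 lower with TMM. miR-143-3p, abundant in smooth muscle and fibroblasts, was 2.12-fold higher (2.05 to 2.19) and its cluster partner miR-145a-5p 2.98-fold (2.46 to 3.57), but miR-143-3p left the rule under DESeq2 factors, both left it under TMM, and both were lower under the authors' totals.

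Of 9 let-7 members 1 was lower and 8 were neither, with a median of -0.16 (percentile 42.1), while 6 were lower with TMM and 9 under the authors' totals. Of 11 members of the miR-17-92 cluster and its paralogues, which promote proliferation, none met the rule, with 7 neither and 4 not resolved (median -0.43, percentile 40.3), while 5 were lower with TMM and 9 under the authors' totals. The ratio of miR-92a-3p was 0.740 (0.670 to 0.815). Of 7 melanocyte-lineage miRNAs 2 were higher, miR-148a-3p and miR-182-5p, and 3 were not resolved. The median of 0.69 (percentile 86.5) turned negative under TMM, with 1 higher and 1 lower, and under the authors' totals, with none higher and 4 lower. Of 11 melanoma-associated miRNAs 4 were higher, which were miR-690, miR-221-3p, miR-222-3p and miR-532-5p, and miR-30d-5p was lower. Their median of 0.30 (percentile 87.7) turned negative under the same scalings, with 1 higher and 3 lower with TMM and 1 higher and 10 lower under the authors' totals, and with DESeq2 2 were lower. Of 7 members of the miR-10, miR-99/100 and miR-125 families 1 was higher, miR-100-5p, and 2 were lower, with miR-10b-5p at a ratio of 1.23 (1.17 to 1.29) and a family median of -0.21 (percentile 37.7). With TMM 5 and with DESeq2 3 were lower, and under the authors' totals 6 were lower and none higher. The miR-181 family had 3 members that were neither and 1 not resolved (median -0.34, percentile 38.6), while 3 were lower with TMM and 3 under the authors' totals. In the Dlk1-Dio3 imprinted cluster, a set of miRNAs read from the maternal chromosome, 2 of 5 members were higher under every scaling tried and 3 were not resolved. These were miR-127-3p at 48.3-fold (31.6 to 72.0) and miR-379-5p at 49.6-fold (25.3 to 91.3), on 32 and 14 exosome reads. Of 5 liver, muscle and brain miRNAs 2 were higher, miR-122-5p and miR-138-5p, while 1 was higher and 3 were lower under TMM, and none was higher and 4 were lower under the authors' totals. In the miR-15/16 family 1 of 6 was higher, while 1 was lower with DESeq2, and none was higher and 1 and 5 were lower with TMM and the authors' totals. In the miR-34 family 1 of 2 and in the non-canonical list 1 of 5 was lower, and all of both lists were under the authors' totals. In the miR-29 family 1 of 3 was lower, against 2 with TMM and the authors' totals and none without the most abundant miRNAs. The hypoxia list had 1 of 2 neither and 1 not resolved, and 1 was lower with TMM and the authors' totals. The 2 entries resembling rRNA or tRNA fragments were not resolved, and both were lower under the authors' totals. The 3 epithelial members, the 2 erythroid members and the 1 member of the miR-290 and miR-302 clusters were not resolved under any scaling tried. The leukocyte, Sfmbt2 and H19 and Igf2 lists had 0 members with enough reads.

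**Figure D2:**
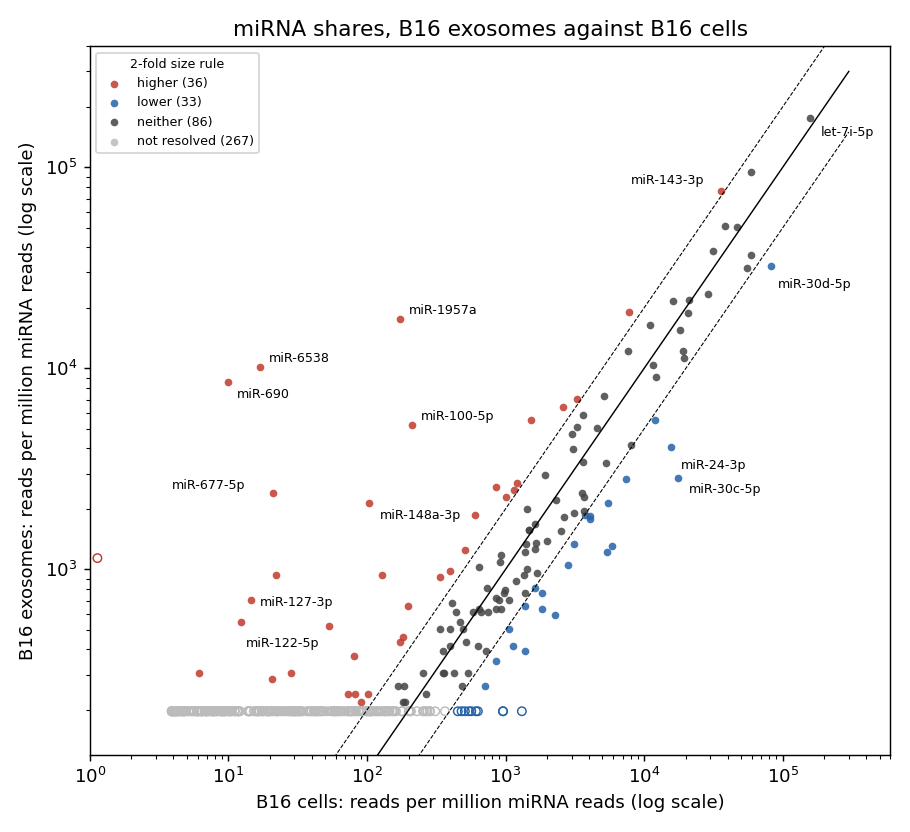
Each point is a miRNA with 30 or more reads over the B16 exosome and B16 cell libraries, placed by its RPM of miRNA reads in cells (horizontal, log scale) and exosomes (vertical, log scale), with 1 library per axis, lines at equal share and 2-fold, and open circles for a listed 0 placed at 9 reads. 36 miRNAs are higher and 33 lower under the main scaling (16 and 93 with TMM, 9 and 257 with the authors' totals), and the row of circles at 9 exosome reads holds the 267 that were not resolved.

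The B16 exosome library was set against the JB6 exosome library, which asks how vesicles of a melanoma line differ from those of a normal skin line. Cell line, strain and disease state went together in this comparison. miR-122-5p was 478-fold lower in B16 exosomes (321 to 746), miR-148a-3p was 102-fold lower (83.3 to 125.1), and miR-423-5p was 63.4-fold lower (44.2 to 94.7). miR-1957a was 2729-fold higher (1885 to 4101), miR-103-3p was 242-fold higher (197 to 297), and miR-9-5p, a miRNA of neural tissue, was 168-fold higher (146 to 194). miR-690 had 390 reads in B16 exosomes and a listed 0 in JB6 exosomes, which made it at least 4265-fold higher, and miR-211-5p had 83 reads against a listed 0, at least 908-fold higher.

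Of 300 miRNAs with 30 or more reads 94 were higher and 35 lower, 25 were neither and 146 were not resolved. The balance turned with the scaling. TMM gave 61 higher and 97 lower, DESeq2 size factors gave 57 and 109, and the authors' totals gave 40 and 153. Every log2 ratio moved by -2.37 with TMM, -2.70 with DESeq2, -0.54 without the most abundant miRNAs and -3.89 with the authors' totals. Across the 131 miRNAs listed in both, the Spearman coefficient was 0.42 and the Pearson coefficient on the log2 scale was 0.44, again across miRNAs.

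Among the higher miRNAs, miR-677-5p had 110 reads against a listed 0 and was at least 1203-fold higher, miR-145a-5p was 226-fold higher (161 to 320) and miR-26b-5p 136-fold higher (115 to 162). miR-184-3p, a miRNA of eye epithelia, was 61.1-fold higher (52.0 to 71.7), miR-16-5p, a brake on the cell cycle, was 50.9-fold higher (40.6 to 63.5), let-7g-5p was 48.8-fold higher (45.8 to 52.0), miR-26a-5p was 46.3-fold higher (42.9 to 50.02) and miR-7a-5p was 44.2-fold higher (41.1 to 47.5). These stayed higher under every scaling tried. miR-21a-5p was 4.07-fold higher (3.87 to 4.28) and miR-143-3p was 2.37-fold higher (2.29 to 2.45), and both ratios fell below 1 under TMM, DESeq2 and the authors' totals. miR-155-5p, with 88 reads in JB6 exosomes and a listed 0 in B16 exosomes, was not resolved.

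Among the lower miRNAs, several with a listed 0 in B16 exosomes were abundant in JB6 exosomes. miR-615-3p, from an intron of Hoxc5 (chromosome 15, 103014910 to 103015001), had 59466 reads and was at least 67.1-fold lower. miR-486a-5p and miR-486b-5p, which are abundant in red blood cells and muscle, had identical counts of 32994 and were at least 37.2-fold lower, or 19.6-fold by that limit. miR-125b-1-3p was at least 36.0-fold lower and miR-206-3p, a skeletal-muscle miRNA with 16619 reads, at least 18.8-fold. miR-669c-5p, whose hairpin is annotated in an intron of Sfmbt2 (chromosome 2, 10509296 to 10509404), was at least 20.3-fold lower. Stretches of that hairpin recur in 27 other annotated genes. let-7d-3p was 20.2-fold lower (13.9 to 30.3), miR-320-3p, another miRNA made without Drosha, 19.1-fold (12.7 to 30.2) and miR-99b-5p 11.5-fold (9.71 to 13.8). Mir122 lies at chromosome 18, 65248861 to 65248926, in an exon of a long non-coding RNA, Mir148a at chromosome 6, 51269812 to 51269910, outside annotated genes, and Mir423 at chromosome 11, 77078064 to 77078172, in an intron of Nsrp1.

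By list, 8 of 9 let-7 members were higher and 1 was neither, with a median of 3.22 (percentile 87.0) that fell to 0.86 with TMM and 0.52 with DESeq2 and turned to -0.67 under the authors' totals. With TMM 4 were higher and 1 lower, with DESeq2 4 and 2, and under the authors' totals 2 and 4. let-7f-5p was 40.4-fold higher (39.0 to 41.9) and let-7i-5p 19.4-fold (18.95 to 19.9), while the ratio of let-7b-5p was 0.801 (0.731 to 0.877). All 5 miR-30 members were higher, with a median of 5.01 (percentile 94.99) that was positive under all 4 other scalings, although miR-30d-5p alone, at 6.14-fold (5.82 to 6.48), fell below 1 under DESeq2 and the authors' totals, and under the latter 3 of the 5 were higher and 1 lower. miR-30b-5p was 253-fold higher (164 to 399) and miR-30a-5p 32.2-fold (30.8 to 33.8). Of 8 members of the miR-17-92 cluster and its paralogues 5 were higher, 1 was lower, 1 was neither and 1 was not resolved, with a median of 4.50 (percentile 84.2) that was positive under all 4 other scalings, with 5 higher and 2 lower with TMM and DESeq2 and 2 of each under the authors' totals. miR-17-5p was 33.2-fold higher (25.7 to 42.5) and miR-93-5p 25.6-fold (21.4 to 30.6), while miR-92a-3p was 5.85-fold lower (5.31 to 6.45). Of 7 members of the miR-10, miR-99/100 and miR-125 families 3 were lower and 4 neither, with a median of -0.90 (percentile 5.64), while all 7 were lower with TMM, DESeq2 and the authors' totals and 5 without the most abundant miRNAs. Under the main scaling miR-125b-5p was 8.18-fold lower (5.18 to 13.8) and miR-125a-5p 7.47-fold (4.78 to 12.4), while the ratio of miR-10b-5p was 0.926 (0.883 to 0.971) and that of miR-99a-5p 0.966 (0.902 to 1.03).

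Of 5 melanocyte-lineage miRNAs 3 were higher, which were miR-211-5p, miR-148b-3p and miR-182-5p, and miR-148a-3p was lower. Their median of 3.72 (percentile 84.1) turned to -0.17 under the authors' totals, where 2 were higher. Of 12 melanoma-associated miRNAs 7 were higher, 1 was lower, 2 were neither and 2 were not resolved. That median of 2.19 (percentile 69.3) turned to -0.18 with TMM, -0.52 with DESeq2 and -1.70 under the authors' totals, with 2 higher under each and 4, 4 and 8 lower. Of 6 mesenchymal miRNAs 3 were higher, 1 was neither and 2 were not resolved, with a median of 1.24 (percentile 43.2) that turned to -1.12, -1.46 and -2.65 under the same scalings, with 1 higher and 4 lower under each, and 1 was higher without the most abundant miRNAs. In the Dlk1-Dio3 cluster 13 of 17 members were not resolved, 2 were lower, 1 was higher and 1 was neither, while none was higher and 9 were lower with TMM, 10 with DESeq2 and 12 under the authors' totals. The lower members were miR-409-3p, at least 8.42-fold, and miR-543-3p, at least 7.91-fold, and the higher member, miR-379-5p, left the rule under all 4 other scalings. Under the main scaling the median over all 17 was at most 1.16, which leaves its direction open. Of 3 erythroid entries 2 were lower, the identical miR-486a-5p and miR-486b-5p, and miR-451a was not resolved, while all 3 were lower with TMM, DESeq2 and the authors' totals. Of 5 liver, muscle and brain miRNAs 2 were lower, miR-122-5p and miR-206-3p, and 1 was higher, miR-9-5p, with a median over all 5 of at most -0.20, and 3 were lower with TMM and DESeq2 and 4 under the authors' totals. The miR-23/27/24 clusters had 2 of 5 higher and 3 neither, with a median of 0.56 (percentile 42.3) that was negative under TMM, DESeq2 and the authors' totals, each with 3 lower, and 2 were lower without the most abundant miRNAs. All 3 miR-181 members were higher, but none was under TMM, DESeq2 or the authors' totals, where 1 was lower.

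The remaining lists had few members. In the Sfmbt2 list 1 of 5 was lower, against 2 under the authors' totals, and the others were not resolved. In the non-canonical list 1 of 4 was higher and 1 lower, while none was higher under any of the 4 other scalings, and 2 were lower with TMM and DESeq2 and 3 under the authors' totals. The single miR-29, miR-15/16 and hypoxia members were higher. The miR-29 member was neither with TMM and DESeq2. Under the authors' totals the miR-29 member was lower, the hypoxia member was neither and the miR-15/16 member stayed higher. Of 2 entries resembling rRNA or tRNA fragments 1 was higher, and it was neither under the authors' totals. The single miR-34 member was neither, and lower under TMM, DESeq2 and the authors' totals. The single leukocyte member and the single member of the miR-290 and miR-302 clusters were not resolved, and the epithelial and H19 and Igf2 lists had 0 members with enough reads.

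**Figure D3:**
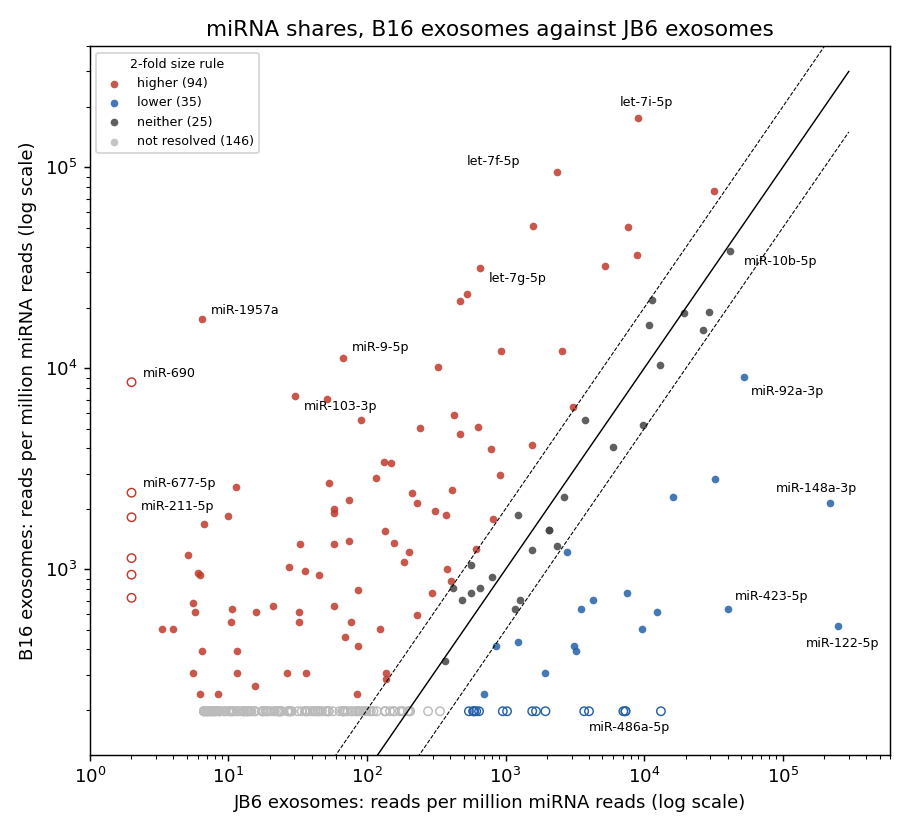
Each point is a miRNA with 30 or more reads over the exosome libraries, placed by its RPM of miRNA reads in JB6 exosomes (horizontal, log scale) and B16 exosomes (vertical, log scale), with 1 library per axis, lines at equal share and 2-fold, and open circles for a listed 0 placed at 9 reads. 94 miRNAs are higher and 35 lower under the main scaling (61 and 97 with TMM, 57 and 109 with DESeq2 factors, 40 and 153 with the authors' totals), and miR-122-5p and miR-148a-3p lie far to the lower right.

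Setting each exosome library against the B16 cells asks which miRNAs were over-represented in both. The miRNAs higher in both numbered 13, and comprised miR-127-3p, miR-379-5p, miR-100-5p, miR-148a-3p, miR-122-5p, miR-199a-5p, miR-6538, miR-221-3p, miR-222-3p, miR-146b-5p, miR-151-3p, miR-28a-3p and miR-1981-5p. For miR-122-5p, carry-over from the JB6 exosome library could supply all 24 B16 exosome reads. The ratio of miR-100-5p was 24.8 in B16 exosomes and 46.5 in JB6 exosomes, that of miR-127-3p was 48.3 and 87.1, and that of the related miR-221-3p and miR-222-3p, which act on the cell-cycle inhibitor p27, was 2.72 and 2.38 for the former and 3.31 and 9.62 for the latter. The B16 exosome ratios of miR-221-3p and miR-222-3p fell below 1 under the authors' totals. Independent lists of 35 and 57 miRNAs among the 421 tested in both would share 4.74, and 100 simulated pairs of unchanged libraries set against the B16 cells shared at most 0, which follows from the few calls that unchanged libraries give and is no baseline for the overlap. The value of 4.74 is no baseline either, since a miRNA with a listed 0 in B16 exosomes could not be called higher there. In that comparison 267 of 422 miRNAs had such a 0 and were not resolved. The comparisons use the same B16 cell library, which cannot be split, so part of the overlap may come from it. JB6 cells were not analysed here, and the JB6 ratios therefore mix cell line and fraction. The count was 8 with TMM factors, 8 when the interval bound itself had to reach 2-fold, and 3 under the authors' totals. The miRNAs lower in both numbered 27, with the identical let-7a-1-3p and let-7c-2-3p counted separately, where independent lists would share 23.8. That value is again no baseline, since most miRNAs with a listed 0 in B16 exosomes were not resolved. miR-30c-5p, miR-30d-5p, miR-30e-5p, miR-24-3p, miR-27a-3p, miR-27b-3p and let-7d-5p were among them.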

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

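The share described here was not planned and was computed after the values were seen. In the B16 exosome library 94.6% of the authors' per-library RPM total lay outside the miRNA counts, against 9.12% in B16 cells and 20.1% in JB6 exosomes. It stood out far above the level of the other libraries, in a part that no miRNA count includes. That part enters the comparisons only through the authors' totals as scaling. The shifts of log2 ratios under that scaling, -4.08 against B16 cells and -3.89 against JB6 exosomes, restate these shares. miRNA reads made up 5.39% of that total in B16 exosomes, 90.9% in B16 cells and 79.9% in JB6 exosomes. What the other reads were is not given in the sources used here, and no technical or biological explanation was tested.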

How the results depend on the processing

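The authors' totals as scaling and the thinned libraries were chosen after the data were seen, and the other alternatives were planned. No paired analysis was possible because each group held 1 library and the labels carry no replicate numbers, and for the same reason no library could be left out in turn. Scaling had the greatest effect among the settings tried. miRNAs higher and lower in B16 exosomes than in B16 cells numbered 16 and 93 with TMM, 9 and 257 with the authors' totals and 23 and 14 when the interval bound had to reach 2-fold, against 36 and 33. Those higher and lower in B16 than in JB6 exosomes numbered 61 and 97 with TMM, 57 and 109 with DESeq2 and 40 and 153 with the authors' totals, against 94 and 35. miRNAs higher in both exosome libraries numbered 8 with TMM, 3 with the authors' totals and 8 with the stricter bound, against 13. A scaling multiplies every ratio of a comparison by a constant, so these counts move by construction. Under the authors' totals that constant is set by the miRNA share of each total, which was 5.39% in B16 exosomes. Minimums of 10, 100 or no reads and summed families kept each count within 1.5 times.

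Under the authors' totals the log2 ratio of B16 exosomes to B16 cells turned to -0.30 for miR-199a-5p, -0.77 for miR-122-5p, -0.64 for miR-5100, -1.19 for miR-3535, -2.99 for miR-143-3p and the mesenchymal median, -2.50 for miR-145a-5p, -2.63 for miR-221-3p and -2.35 for miR-222-3p. For B16 against JB6 exosomes, miR-30d-5p turned to -0.085 with DESeq2 and -1.27 with the authors' totals, miR-21a-5p to -0.34 with TMM, -0.68 with DESeq2 and -1.86 with the authors' totals, and miR-143-3p, with the mesenchymal median, to -1.12, -1.46 and -2.65. The melanoma-associated median turned to -0.18, -0.52 and -1.70 under the same settings, and the let-7 and melanocyte medians to -0.67 and -0.17 with the authors' totals. Of 83 ratios named in the text, 6 changed sign with TMM, 3 with DESeq2, 15 with the authors' totals and 0 without the most abundant miRNAs, and of those that met the size rule 2, 3, 11 and 0 did. Of 19 list medians over well-covered members 5, 3, 8 and 0 changed sign, and of those at least 2-fold in size 2, 2, 5 and 0. Nearly all of these scalings lower the ratios of B16 exosomes, so negative values had little room to turn and their sign says nothing about stability. The minimum-read settings leave single ratios, and medians over well-covered members, as they are. Depth limits the B16 exosome library most, where 267 of 422 and 146 of 300 miRNAs could not be resolved.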

Other observations

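The tests of scaling, of carry-over between libraries, of red blood cells and leukocytes and of serum were chosen after the results were seen, while those of repeated sequence and of GC content were set before. JB6 exosomes set against B16 cells differ in both cell line and fraction, with 1 library each, and against the main scaling every log2 ratio moved by 1.35 with TMM, 2.58 with DESeq2, 0.62 without the most abundant miRNAs and -0.19 with the authors' totals. The Dlk1-Dio3 imprinted cluster stood out. Of its 19 members with enough reads 18 were higher in JB6 exosomes, with a median log2 ratio over all 19 of at least 4.47, but 10 of the 18 were listed at 0 in B16 cells, and with 30 or more reads such a member is higher by construction under the main scaling. miR-409-3p had 7462 reads against 18, a 731-fold higher share (462 to 1234), and miR-543-3p had 7009 reads against a listed 0, at least 1373-fold higher. Of the Sfmbt2 intronic cluster, which is rich in rodent placenta, 11 members were listed in JB6 exosomes and 0 in either B16 library, led by miR-669c-5p with 18001 reads, at least 3526-fold higher. Stretches of the miR-669c hairpin recur in 27 other annotated genes, so these reads may not come from that locus. Entries of this list were matched by name prefix alone. The 3 erythroid entries with 30 or more reads were higher, with miR-486a-5p at 32994 reads against 153 and miR-451a at 606 against 13. All 5 members of the miR-30 family were lower under every scaling, and all 6 of the miR-15/16 family were except with DESeq2, where 5 were, with median log2 ratios of -6.56 and at most -4.85. miR-9-5p had 302 reads in JB6 exosomes and 155066 in B16 cells, a 291-fold lower share, and the melanocyte miRNA miR-211-5p had 21080 reads in B16 cells and a listed 0 in JB6 exosomes.

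The arm of the hairpin that dominated also differed between these libraries. Among 57 hairpins with both arms listed, the 3p share differed by a median of 6.97 percentage points, and the more abundant arm differed in 10. For let-7d the 3p arm held 9.56% of the reads in B16 cells (9.30 to 9.83), 22.2% in B16 exosomes (15.3 to 30.5) and 98.2% in JB6 exosomes (98.1 to 98.3). For miR-423 it held 81.5% in B16 cells (81.1 to 81.9), 73.6% in B16 exosomes (64.4 to 81.6) and 1.96% in JB6 exosomes (1.90 to 2.03). For miR-30e the more abundant arm differed from the cells in both exosome libraries. Its 3p arm held 31.6% in B16 cells (31.1 to 32.1), 59.9% in B16 exosomes (51.6 to 67.7) and 63.6% in JB6 exosomes (58.8 to 68.3). For miR-145a the 3p arm held 21.1% in B16 cells and 92.2% in JB6 exosomes, and for miR-23b 98.7% and 17.8%. A share within a hairpin does not depend on the scaling.

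In B16 exosomes 11 miRNAs were at least 10-fold higher than in B16 cells by the interval bound, including miR-690, miR-6538, miR-1957a and miR-677-5p. The choice of scaling stays open for the set: under the authors' totals 9 of the 11 still met the size rule, with ratios from 2.51 for miR-3473a (1.76 to 3.53) to at least 59.4 for miR-5126 and the lowest interval bound, 1.5, for miR-379-5p, while miR-100-5p at 1.47 and miR-148a-3p at 1.23 did not, so their excess may rest on the total used. Carry-over from the JB6 exosome library is argued against for the 5 that were also higher there, since it allows 2.59% of their pooled reads, 21.2% for miR-148a-3p (upper limit 31.6%) and 0.392% or less for each of the other 4. The carry-over rate was set by miR-122-5p, which is not among the 11. It therefore allows all 24 B16 exosome reads of miR-122-5p, whose excess over the cells stays open to it. Repeated sequence stays open. The hairpins of miR-690, miR-3473a and miR-3470b, 3 of the 11, share stretches with 10 or more other genes. Among other miRNAs 2 of 134 do (Fisher's exact test, two-sided, p = 0.00304). Arms of the same hairpin have the same value and were counted separately, so that test treats them as independent when they are not. The other 8 of the 11 do not reach that cutoff, though stretches of miR-1957a and miR-5126 recur in 4 and 2 other genes. Genes that overlap a hairpin were left out, so the snoRNA annotated at Mir677 did not count. Selective loading into vesicles is a hypothesis that these tables leave untested.

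miR-122-5p and miR-148a-3p held 25.1% and 21.8% of the JB6 exosome reads. Red blood cells and leukocytes as their main source are argued against, since the lower of the pair, miR-148a-3p, lay 29.7-fold above miR-486a-5p (29.4 to 30.02), the most abundant of the 9 erythroid and leukocyte entries there. A small amount of red-cell RNA stays open, since miR-486a-5p and miR-451a were 380-fold and 82.2-fold higher than in B16 cells, and platelets were not tested. A linear trend with GC content did not account for the pair, while other effects of GC stay open. The trend of the JB6 to B16 exosome log2 ratio with GC over 127 miRNAs was weak (Spearman coefficient 0.22). The log2 ratios of miR-122-5p and miR-148a-3p were 8.90 and 6.67. They lay 11.6 and 9.62 log2 units above that trend, where distances had an SD of 3.13. Both therefore passed the limit set before, which was 10-fold above the trend. The pair was picked for its extreme values, so it would lie far above any weak trend. GC was that of the hairpin side holding the miRNA, not of the mature miRNA. Carry-over from culture serum may contribute and cannot be told apart from a property of the JB6 line, because no serum or medium library was analysed here. B16 exosomes held 24 reads of miR-122-5p, which carry-over from the JB6 exosome library could supply. Whether both cultures had the same serum is not given in the sources used here. A difference between the cell lines stays among the open explanations, untested.

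The B16 exosome profile followed that of the cells for most abundant miRNAs. Reads of the cell library counted in the exosome library are argued against as the whole cause, since a constant carry-over could make up at most 15.0% of the exosome reads (upper limit 28.5%), set by miR-27a-5p among 73 abundant miRNAs whose ratios ranged 23.9-fold. Whether RNA of broken cells entered the vesicle preparation was not tested.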
